A study of Caenorhabditis elegans with 2 samples.

How the data were processed

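Chromatin immunoprecipitation followed by sequencing was carried out on late embryos of a Caenorhabditis elegans strain that carries a transgene of the transcription factor HLH-15 with a GFP-FLAG tag at its C terminus, and, per the description in the labels, the tagged protein was pulled down with an antibody against GFP. The label for the antibody itself names hlh-15, and the sources used here do not settle which holds. Per the labels, the 2 libraries are biological replicates 1 and 2 of 1 group, embryos of hermaphrodites collected 3 hours after synchronisation by egg bleaching, with chromatin sheared by sonication. The labels give no second group, so no contrast between conditions was made.

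For each of the assemblies ce10 and ce11, 4 peak lists were used: 1 for each replicate, 1 for the pooled replicates, and the list that passed the authors' threshold on the irreproducible discovery rate (IDR), a measure of how well peak ranks hold between replicates. Per the notes deposited with the lists, the replicate and pooled lists were derived from alignments of the immunoprecipitated libraries together with a control library and hold peaks and background as the input of the IDR step, and the IDR list was derived from those lists. The aligner, the peak caller and their versions are not given in the sources used here. The signal value of each peak is the authors' score, whose scale is not stated and differs between lists, so its levels were not compared between lists. It was used to rank and describe peaks within a list, to compare groups of peaks of 1 list on the log2 scale, and to correlate the values of the same peaks between the replicates. The authors also deposited a −log10 q for each peak, which was used only to describe the lists, because it holds 1 value throughout the ce11 IDR list. Every IDR peak of ce11 has the coordinates and the signal value of a pooled peak, and the list is made up of the 407 pooled peaks at or above its lowest signal value. Most peaks have a fixed width, 476 bp for 389 of the 407 IDR peaks, so the summit and not the peak edge was taken as the position of a site. The replicate 2 list holds exactly 30000 peaks in both assemblies. Read numbers are not stated, so the depth is unknown and no interval that needs it is given; Wilson 95% intervals of shares cover counting over peaks or genes only.

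The ce11 lists were the main ones and were set against the same assembly, WBcel235, with the Ensembl release 115 annotation and the NCBI sequence; no coordinates were converted between assemblies. Distances were measured from the summit to the nearest of 29314 transcription start sites (TSS) of 19973 protein-coding genes, and a peak was assigned to the gene of that TSS when it lay within 2 kb. Random expectations came from 1000 shuffles of the summits within their chromosomes, with p-values that cannot fall below 0.001 one-sided or 0.002 two-sided. The shuffles were uniform along the chromosome and do not allow for positions to which reads cannot be mapped. Sequence was read in windows of 100 bp to each side of the summit and in flanking windows of the same width centred 500 bp to each side, and each E-box type or 6-mer was counted together with its reverse complement. Shares of windows were compared with two-sided Fisher's exact tests, with odds ratios computed after adding 0.5 to each cell, and p-values were adjusted by the Benjamini-Hochberg method over the 10 E-box types, over the 2080 6-mers, over the 6 chromosomes, over the 6 annotation classes and over 22 gene lists. The Fisher's tests took windows as independent and ignored that each summit window has its own flanks. Some peaks overlap, the 407 IDR peaks merging into 386, so that some windows may share sequence. Windows at tRNA genes can also repeat sequence, as 112 of the 129 tRNA genes with an IDR peak have an identical copy in the genome. Differences in median log2 signal were tested with two-sided permutation tests of 100000 resamples.

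The groups, the main tests, the gene lists and 36 of the 64 alternatives were fixed before the data were examined, and the other 28 alternatives were added afterwards. The genes named were the nearest protein-coding genes, within 2 kb, of the 25 IDR peaks with the highest signal value, up to 4 members of each gene list with a peak, and hlh-15, hlh-2 and unc-119 whatever their values. The comparison with tRNA and snoRNA genes, with its distance of 100 bp, was chosen after the data were seen, as were the genes named in it. In that comparison distances of 0, 100, 250, 500 and 1000 bp had been looked at, and 4 subsets of peaks had been looked at for motifs. Alternatives covered the assembly, a stricter list made of the 204 strongest IDR peaks, other overlap rules, the strongest 407 peaks of 1 replicate in place of the IDR list, other distances and windows, other control positions and the removal of peaks near the transgene's own genes.

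The scripts were tested on simulated data before use. In 40 simulations with 407 random positions, CAGCTG planted in 5% of the summit windows was recovered in 32 and CAAGTG in 11, and at 10% both were recovered in all 40. Of 27 pan-neuronal genes, 6 planted among the genes with a peak were recovered in 40 of 40 simulations and 3 in 13 of 40, over 19973 genes. Of 140 neuropeptide genes, 6 planted were recovered in 23 of 40. Analyses were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.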

Results

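HLH-15 is a basic helix-loop-helix (bHLH) transcription factor, a family that binds E-boxes, sites of the form CANNTG, usually as a dimer with a partner such as the E protein HLH-2. Its binding sites were mapped in whole late embryos by pulling down a tagged copy, in 2 biological replicates of 1 group. The authors' IDR list held 407 peaks in ce11. The lists that also hold background were far longer, with 17654 peaks in the pooled list, 21250 in replicate 1 and 30000 in replicate 2. Signal values of the IDR peaks ran from 58.9 to 587 with a median of 81.1 and quartiles of 67.0 and 104.5. Read depth is unknown, and the signal value is the authors' score for each peak.

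The replicates shared most of the strongest sites and less of the weaker ones. Of the 407 IDR peaks, 256, or 62.9% (Wilson 95% interval 58.1 to 67.5), overlapped one of the 407 highest-signal peaks of both replicates by at least 1 bp, against a mean of 0.219% for shuffled peaks (permutation test, one-sided p = 0.001, the smallest that the shuffles can give). Among the 204 strongest IDR peaks by pooled signal, which draws on the same libraries, the share was 94.6%. The top lists covered 82.6% of the IDR peaks in replicate 1 and 76.4% in replicate 2. Of the 100 strongest peaks of replicate 1, 71 overlapped one of the 100 strongest of replicate 2, and of the 5000 strongest, 1376, or 27.5%, did so. Across the 405 IDR peaks with a peak in each replicate, Spearman's rho of the replicates' signal values was 0.55 and Pearson's r of log2 values was 0.64. These correlations are across peaks, which are not independent replicates, and the IDR list was itself chosen for agreement between the replicates. Its overlap with their strongest peaks was therefore bound to exceed that of shuffled peaks, so that the permutation test adds no support.

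**Figure D1:**
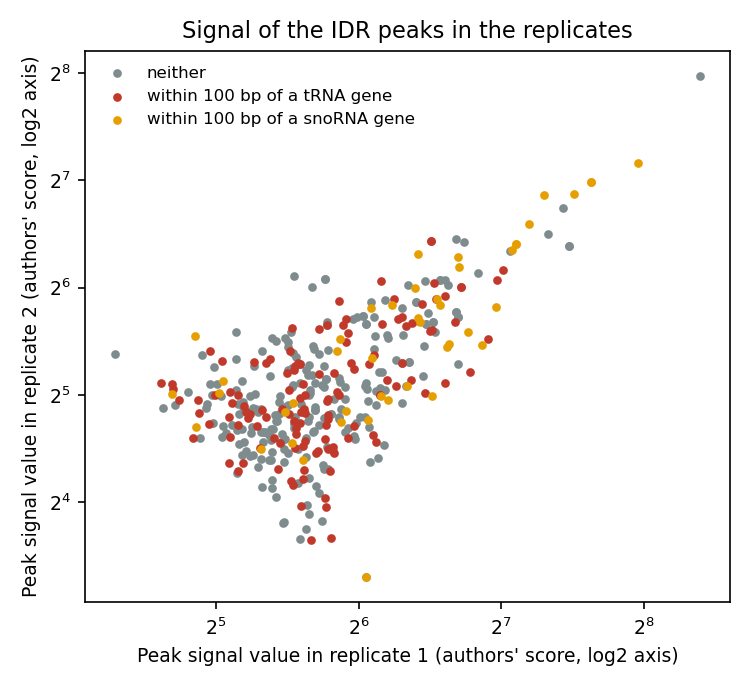
Signal value of each IDR peak in replicate 1 (x axis) and replicate 2 (y axis), both the authors' score on log2 axes, for the 405 peaks found in both lists; colours mark peaks whose summit lies within 100 bp of a tRNA gene or a snoRNA gene. The strongest point in both replicates is the peak upstream of K12H4.5, and rho over all points is 0.55.

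The strongest IDR peak, with a signal of 587, lay on chromosome III at 8043778 to 8044151, with its summit 521 bp upstream of the TSS of K12H4.5 (WBGene00019680). Its signal was 337 in replicate 1 and 251 in replicate 2. Among the 25 strongest peaks, 21 had a protein-coding TSS within 2 kb. Of these, the peaks of ears-2, T13C5.6, M01F1.9, snx-13, vps-51, idhg-1, atx-2 and chaf-2 lay, like that of K12H4.5, in the 1 kb upstream of a TSS and away from tRNA and snoRNA genes. The peak of ears-2 (WBGene00001338), a glutamyl-tRNA synthetase gene, was on chromosome IV at 390335 to 390629, with its summit 27 bp upstream of the TSS and a signal of 281. The gene of an isocitrate dehydrogenase subunit, idhg-1, had a summit 32 bp upstream of its TSS and a signal of 192, and atx-2, the ataxin-2 homologue, had one 75 bp upstream with a signal of 185. The peaks of snx-13, a sorting nexin gene, and vps-51, a gene of a vesicle tethering complex, had signals of 214 and 195. The peak of chaf-2, named for a chromatin assembly factor, had 167.

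The remaining top peaks with a gene in reach lay at small RNA genes. Those assigned to F55C5.17, W03C9.1, sre-23, str-56, T02E1.2, twk-5, mpk-2 and Y43F8C.7 had their summits within 100 bp of a snoRNA gene. Those assigned to C04A11.5, col-181, M02F4.2 and gcy-33 had theirs within 100 bp of a tRNA gene. The peak assigned to sre-23, a chemoreceptor gene, was on chromosome I at 8259407 to 8259685 with a signal of 295, and its summit was 649 bp upstream of the sre-23 TSS but 90 bp from the snoRNA gene ZK265.10. The peak assigned to mpk-2, a MAP kinase gene, had its summit in an intron, 39 bp from the snoRNA gene C04G6.12.

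IDR summits away from tRNA and snoRNA genes were concentrated just upstream of genes. Of all the 407 summits, 260, or 63.9% (59.1 to 68.4), lay within 1 kb of a protein-coding TSS, against 40.3% of shuffled positions (permutation test, one-sided p = 0.001, the smallest possible). The share was 84.2% of the 234 summits with no tRNA or snoRNA gene within 100 bp, 35.9% of the 128 at tRNA genes and 37.8% of the 45 at snoRNA genes, a division made after the data were seen. It was 45.9% among the 17247 pooled peaks below the IDR threshold (odds ratio 2.08, 95% interval 1.70 to 2.55, Fisher's exact p = 7.97e-13), a comparison added after the data were seen. In the next 407 pooled peaks by signal the share was still 61.2% (56.4 to 65.8) over all peaks. These blocks differ in make-up, with 31.4% of IDR summits at tRNA genes and 11.1% at snoRNA genes, against 10.3% and 1.47% in the next block. Whether the share away from such genes drops at the threshold cannot be read from these values. By class, 56.5% of summits lay within 1 kb upstream of a TSS or in a 5′ UTR, against 22.97% of shuffled positions. A position in several classes was counted in the upstream and 5′ UTR class first, then in coding exons, 3′ UTRs, introns and exons of non-coding genes. Exons of non-coding genes outside protein-coding transcripts and their upstream 1 kb thus held 9.58% against 2.12%. Summits inside tRNA genes, 18.4% of all, were therefore spread over several classes. Coding exons held 1.72% against 20.9%, introns 21.9% against 28.7%, intergenic sequence 10.3% against 22.9%, and 3′ UTRs 0 of 407 summits against 2.39%. All 6 classes differed from the shuffles (two-sided permutation test, adjusted p between 0.0024 and 0.004). Of the 234 summits away from tRNA and snoRNA genes, 80.8% (75.2 to 85.3) were in the upstream and 5′ UTR class, against 23.4% of shuffled positions (permutation test, adjusted p = 0.003). Introns then held 8.12%, and the class of non-coding exons held 3.42% and no longer differed from the shuffles (permutation test, adjusted p = 0.230).

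**Figure D2:**
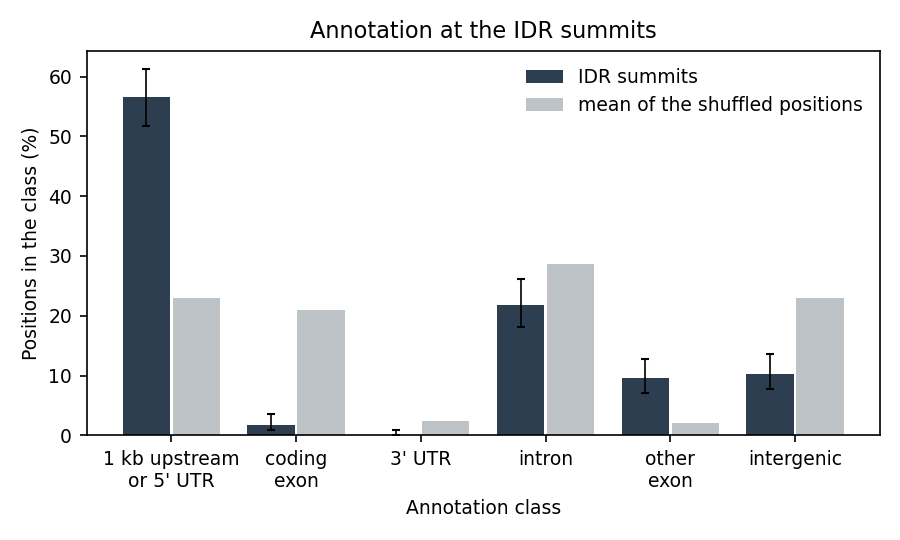
Share of the 407 IDR summits in each annotation class (dark bars, with Wilson 95% intervals) and the mean share of 1000 shuffles within chromosomes (light bars), in percent of positions. The upstream and 5′ UTR class holds 56.5% of summits against 22.97% of shuffled positions, and coding exons hold 1.72% against 20.9%.

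Chromosome III carried more peaks than its length gives and chromosome V fewer. Chromosome III held 75 peaks, or 18.4% (14.96 to 22.5), with 13.7% of the genome length (exact binomial test, adjusted p = 0.023), and chromosome V held 54, or 13.3%, with 20.9% of the length (adjusted p = 0.00054). The X chromosome held 87, or 21.4%, with 17.7% of the length, which did not pass the exact binomial test (adjusted p = 0.0887). Without the peaks at tRNA and snoRNA genes, a setting added after the data were seen, X held 23 of 234 peaks, or 9.83%, which is below its share of the length (exact binomial test, adjusted p = 0.0032).

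A large part of the IDR list lay at short non-coding RNA genes, which was seen in the data and then measured. Within 100 bp of a tRNA gene lay 128 summits, or 31.4% (27.1 to 36.1), against 0.184% of shuffled positions, and within 100 bp of a snoRNA gene 45, or 11.1% (8.37 to 14.5), against 0.124% (permutation tests, two-sided p = 0.002 each, the smallest possible; adjusted p = 0.005 over 10 gene types). Counting only summits inside the gene, the shares were 18.4% for tRNA genes and 1.72% for snoRNA genes. No summit was in both groups, so that they made up 173 peaks, or 42.5% (37.8 to 47.4). Small nuclear RNA genes were within 100 bp of 6 summits and microRNA genes of 2 (permutation tests, adjusted p = 0.005 and 0.143). Pseudogenes were near 3 summits, or 0.737%, against 3.29% of shuffled positions (permutation test, adjusted p = 0.008). Ribosomal RNA genes were near 0 of the 407, against 0.0128% of shuffled positions, so that no lack could have been seen. The IDR list reached 21.1% (18.03 to 24.5) of the 612 annotated tRNA genes, and 44 of 346 snoRNA genes, 12.7% (9.61 to 16.6). The pooled list, which also holds background, reached 310 of the tRNA genes, or 50.7%, and 94 of the snoRNA genes, or 27.2%. Of the 612 tRNA genes 276, or 45.1%, are on X, and 64 of those had an IDR peak.

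Summits at tRNA genes lay in or beside the gene, at a median of 18 bp downstream of its 5′ end with quartiles of -7 and 49 bp. Those at snoRNA genes lay mostly in front, at a median of -39 bp, with 35 of 45 upstream of the 5′ end. The strongest peak at a snoRNA gene was on chromosome V with its summit at 12303649, inside C51F7.4 (12303599 to 12303693), and had a signal of 388, second among all IDR peaks. The strongest at a tRNA gene was on X with its summit at 13665574, inside a tRNA-Leu gene (WBGene00000308, 13665555 to 13665673), and had a signal of 194. Median signal was 118.7 at snoRNA genes and 78.4 at the 234 peaks near neither kind, a log2 difference of 0.60 (95% bootstrap interval 0.31 to 0.90; permutation test, adjusted p = 3e-05), while the peaks at tRNA genes had a median of 80.2 (log2 difference 0.03, -0.10 to 0.15, adjusted p = 0.747).

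Both groups thinned out below the IDR threshold. In the next 407 pooled peaks by signal, 10.3% of summits were at tRNA genes and 1.47% at snoRNA genes, and among all 17247 pooled peaks below the threshold 1.06% and 0.336%. In the strongest 407 peaks of a single replicate, tRNA genes accounted for 28.7% in replicate 1 and 24.1% in replicate 2, and snoRNA genes for 10.1% in each.

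**Figure D3:**
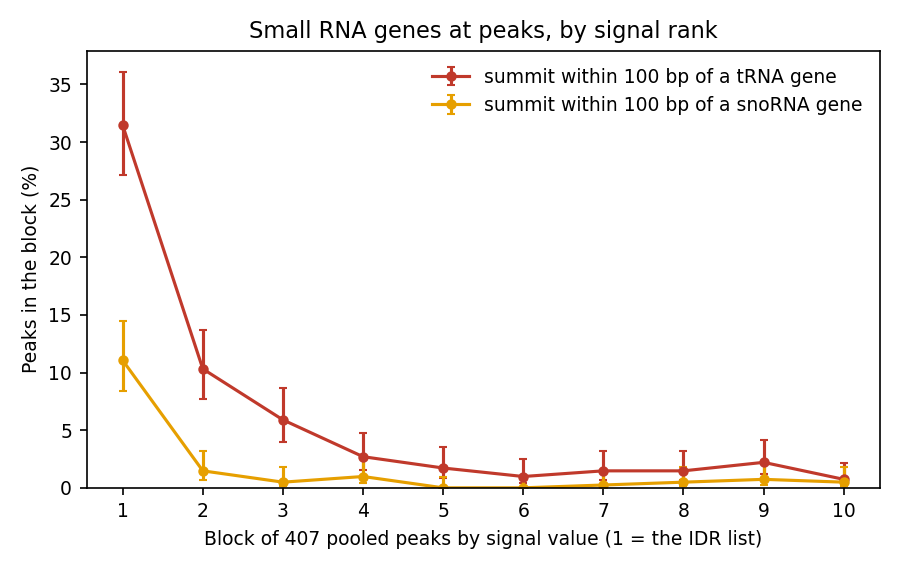
Share of pooled peaks with the summit within 100 bp of a tRNA gene or a snoRNA gene (y axis, percent, with Wilson 95% intervals) in successive blocks of 407 peaks ordered by signal value (x axis, block 1 is the IDR list). The tRNA share falls from 31.4% in block 1 to 10.3% in block 2, and the snoRNA share from 11.1% to 1.47%.

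No E-box type passed the test at the summits. The type with the smallest p, CAAGTG, was in 12.04% of summit windows and 7.37% of flanking windows (odds ratio 1.72, 1.16 to 2.56, Fisher's exact adjusted p = 0.103). CACCTG was in 3.19% against 6.27%, CAGCTG in 3.19% against 4.05% and CACATG in 11.5% against 8.23%. These 2 types, CAAGTG above and CACCTG below the flanks, had an unadjusted p under 0.05. Any E-box at all was in 51.6% (46.7 to 56.4) of summit windows and 55.9% of flanking windows (Fisher's exact p = 0.161). IDR peaks with CAAGTG did not differ detectably in signal from those without, with a median log2 difference of 0.07 (-0.12 to 0.28, permutation p = 0.459, 49 against 358 peaks). The count of types past the threshold moved with the windows and controls: CAAGTG passed in windows of 50 bp to each side, in 9.09% against 4.05% (Fisher's exact adjusted p = 0.00598). In windows of 200 bp to each side it did not, in 18.2% against 14.5% (Fisher's exact adjusted p = 0.160), and CACATG passed there. Both CAAGTG and CACATG passed against 4070 control positions matched on TSS distance, but in sets of 814 of these, as many as the flanking windows, CAAGTG passed in 2 and CACATG in 3 of 5 sets. Against 4070 windows matched on GC content, a control added after the data were seen, CAAGTG did not pass, in 12.04% against 10.15% (odds ratio 1.22, 0.89 to 1.67, Fisher's exact adjusted p = 0.290). In the same comparison CACATG passed above the controls, though in 1 of 5 sets of 814 windows, and CACCTG and CAGATG passed below them, CAGATG in 4.91% against 12.06% (Fisher's exact adjusted p = 3.76e-05).

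**Figure D4:**
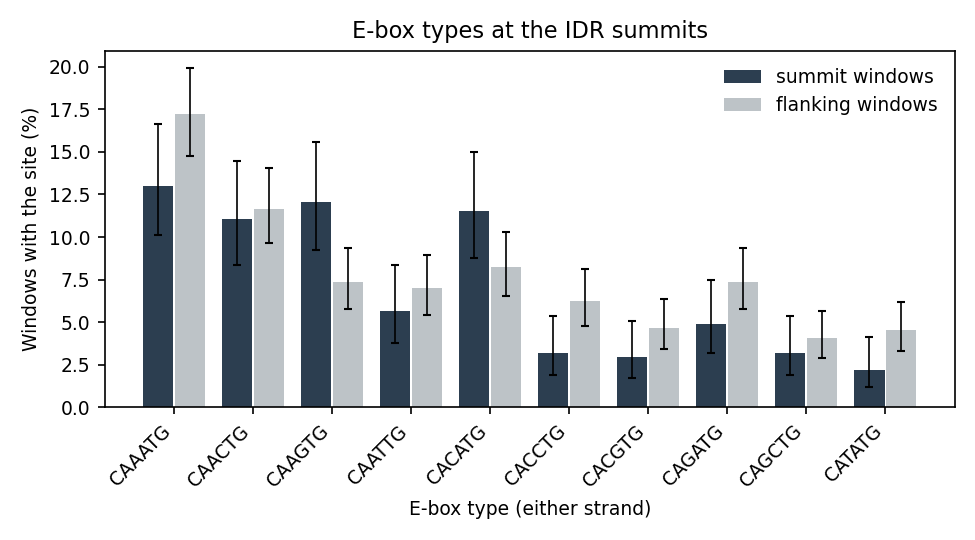
Share of windows (y axis, percent) with each of the 10 E-box types (x axis, either strand) in 407 summit windows (dark bars) and 814 flanking windows (light bars), with Wilson 95% intervals. CAAGTG is in 12.04% against 7.37% and CACCTG in 3.19% against 6.27%, and no type passes the adjusted test.

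The search over all 6-mers found 384 more frequent and 248 less frequent at the summits. The leading one was CGAACC, in 26.04% of summit windows against 3.44% of flanking windows (odds ratio 9.75, Fisher's exact adjusted p = 1.49e-27), followed by CCCCGC with 15.2% against 0.983% and GTTCGA with 29.7% against 7.74%. CGAACC and GTTCGA overlap the sequence GGTTCGA of the B box, an internal promoter element of tRNA genes. Being part of the gene, the B box tends to be in any window over a tRNA gene. The excess of these 6-mers at tRNA genes thus restates where the summits lie, and no comparison with tRNA genes without an IDR peak is given. At the 128 peaks at tRNA genes, 67.2% of summit windows held CGAACC against 2.73% of their flanks, and at the 45 peaks at snoRNA genes 28.9% against 5.56%. At the 234 peaks near neither, CGAACC was in 2.99% against 3.42%, and 213 of the 6-mers passed, led by CCGCAC, in 20.1% against 1.71% (Fisher's exact adjusted p = 2.31e-13), and CGCACA, in 25.6% against 4.27%. Summit windows had a median GC content of 44.3% and flanking windows 36.3%. Against windows matched on GC content, a control added after the data were seen, CGAACC was in 26.04% against 5.28% at all IDR peaks (odds ratio 6.32, Fisher's exact adjusted p = 1.94e-33). CCCCGC was in 15.2% against 4.37%, its odds ratio falling from 17.2 against the flanks to 3.94, and CCGCAC was in 20.1% against 3.72% at the 234 peaks (odds ratio 6.52, Fisher's exact adjusted p = 2.39e-15). At the 234 peaks 367 of the 6-mers passed against these controls, 212 above and 155 below, with 2340 control windows in place of 468.

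Among the 306 genes with an IDR peak within 2 kb, chemoreceptor genes were fewer than among other genes. Of 1298 chemoreceptor genes 7, or 0.539%, had a peak, against 1.60% of other genes (odds ratio 0.36, 0.17 to 0.74, Fisher's exact adjusted p = 0.0219). They included sre-23, str-56, srd-43 and sre-13, with signals of 295, 249, 138 and 121, and each of these 4 peaks lay at a tRNA or snoRNA gene. Without the peaks at such genes, a setting added after the data were seen, 2 of the 1298 had a peak, 0.154% against 1.07% (odds ratio 0.18, 0.05 to 0.62, Fisher's exact adjusted p = 0.00563). With all peaks the difference did not pass against random positions near a TSS, which gave a mean of 13.4 chemoreceptor genes (permutation test, p = 0.0692, adjusted p = 0.761), or among the 204 strongest peaks, with 6 chemoreceptor genes (Fisher's exact adjusted p = 1.0).

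Ribosomal protein genes had 4 of 79 members with a peak, 5.06% against 1.52% of other genes, which did not pass after adjustment (Fisher's exact p = 0.0331, adjusted p = 0.365). Their peaks lay 274 bp upstream of the TSS of rpl-3, 311 bp upstream of rps-24, 371 bp upstream of rpl-15 and 412 bp upstream of rpl-35, with signals of 119.5, 105, 84.6 and 68.9, and none was within 100 bp of a tRNA or snoRNA gene. In the strongest 407 peaks of replicate 2 alone, 6 of the 79 had a peak and the list passed (Fisher's exact adjusted p = 0.0145), and in those of replicate 1 alone 5 had a peak and it did not (Fisher's exact adjusted p = 0.0721).

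The other lists with a member did not pass, each at a Fisher's exact adjusted p of 1.0. Neuropeptide genes had 4 of 140, nlp-76, nlp-4, ins-13 and flp-23, with signals of 134, 107, 73.3 and 68.2. Cuticle collagen genes had 4 of 174, col-181, col-85, col-94 and col-185, with signals between 77.1 and 186, and nuclear receptor genes had 2 of 274, nhr-255 and nhr-41. The peaks of nlp-76, flp-23, col-181, col-85, col-185, nhr-255 and nhr-41 lay within 100 bp of a tRNA gene, and without the peaks at tRNA and snoRNA genes the counts were 2 of 140, 1 of 174 and 0 of 274. Heat shock genes had hsp-1, the constitutive Hsp70 gene, with a signal of 74.3, and the autophagy and lysosome list had atg-18, with 69.7. The other 15 lists had no member with a peak. These were the pan-neuronal genes (27 members), genes of neurotransmitter synthesis and transport (18), ciliated sensory neurons (30), axon guidance (24) and glia (10), bHLH factors (40) and homeobox factors (91). They also took in body wall muscle (24), pharynx (10), epidermal factors (14), intestine (18), germline (22), the Notch pathway (16), the Wnt pathway (20) and histones (50). Lists this small could miss an excess of a few genes, as 3 planted pan-neuronal genes were recovered in 13 of 40 simulations.

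The loci tied to the strain, and that of the partner gene hlh-2, carried no IDR peak. Those of the strain are hlh-15 itself (X, 2412953 to 2413377) and unc-119 (III, 10902641 to 10908935), whose mutation the strain carries and whose wild-type copy serves as the usual transgene marker; hlh-2 is on I at 7190788 to 7193920. Within 50 kb of each, 0 IDR peaks were found. The strongest pooled peak within 50 kb ranked 1602 of 17654 at hlh-15 with a signal of 36.7, 452 at unc-119 with 56.2 and 2834 at hlh-2 with 31.8. In replicate 2, the strongest peak near unc-119 ranked 407 of 30000.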

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

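Settings that involve tRNA and snoRNA genes, GC-matched controls or pooled peaks below the IDR threshold, and the shares of peaks at tRNA and snoRNA genes themselves, were chosen after the data were seen, as were the single replicates at hlh-15 and unc-119. Of 64 alternatives over 13 results, 50 left a result on its side of the threshold, or a count within 1.5 times, and 14 moved it. The 50 include settings that could not move a result, named below. They also include the chromosomes past the test, which went from 2 to 3 without the peaks at tRNA and snoRNA genes. In that setting X went from 21.4% of the peaks to 9.83%, with 17.7% of the length. The replicate overlap, the TSS share and the tRNA and snoRNA shares kept their direction and their side of the threshold under every alternative run for them, and the rank correlation stayed within its interval. For the replicate overlap this was given in advance, because the IDR list was chosen for agreement between the replicates. The stricter list is made of the 204 strongest peaks by construction. The number of E-box types past the threshold, 0 with the main settings, counts types above and below the controls. It was 1 with the stricter list (CACCTG below), 1 in windows of 50 bp (CAAGTG above), 2 in windows of 200 bp (CACATG above, CAGATG below), 3 against controls matched on TSS distance (CAAGTG and CACATG above, CAGATG below) and 3 against controls matched on GC content (CACATG above, CACCTG and CAGATG below). It was 1 without the peaks at tRNA and snoRNA genes (CAAGTG above), 1 at the peaks within 250 bp of a tRNA gene (CACATG above) and 0 at the peaks beyond, and went from 0 to 2 with the strongest peaks of a single replicate (CACCTG and CAGATG below, in replicate 1). The matched controls held 4070 windows and the flanks 814; with 5 sets of 814 a type above the controls passed in 1 set matched on GC content and in 3 matched on TSS distance, while below the controls CAGATG passed in 5 and CACCTG in 4 sets matched on GC content, and in 2 and 0 matched on TSS distance. Without the peaks at tRNA and snoRNA genes 213 of the 6-mers passed instead of 632, with fewer windows tested. The number of gene lists past the threshold, 1 with the main settings, was 0 with the stricter list, which has fewer genes, 0 against random positions near TSSs, and from 1 to 2 with a single replicate. Near hlh-15 or unc-119 there were from 0 to 1 peaks among the strongest 407 of a single replicate. Where no reason is given, the cause was not tested. Leaving out peaks within 50 kb of hlh-15 or unc-119 removed no peak, so that this setting says nothing. Depth is unknown, and how far it limits the number of peaks was not measured.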

Other observations

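The tests on single-copy tRNA genes, on the peaks without tRNA and snoRNA genes, on GC-matched controls and on equal numbers of control windows were chosen after the patterns they bear on were seen in these data. The tRNA genes with an IDR peak were spread over amino acid types, and no type stood out from the others (Fisher's exact tests, adjusted p = 1.0 for each). The shares were 26.5% of 34 tRNA-Ala genes, 20% of 55 tRNA-Gly genes and 11.1% of 27 tRNA-Gln genes, for example. Of the X-linked tRNA genes 23.2% had an IDR peak, against 22.7% on I, 22.8% on II, 23.4% on III, 14.1% on IV and 15.4% on V. Of the IDR summits 29.2% lay within 100 bp of genes that the annotation calls only ncRNA, against 2.36% of shuffled positions (permutation test, adjusted p = 0.005), and 91 of these were also at tRNA or snoRNA genes. The fourth strongest peak of replicate 1, with a signal of 183, was on the mitochondrial genome at 12878 to 13381, and replicate 2, the pooled list and the IDR list held no mitochondrial peak.

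For the first pattern, the excess of IDR peaks at tRNA and snoRNA genes, GC content of the called regions is argued against, because GC-matched pooled peaks below the threshold were at tRNA genes far less often (odds ratio 20.9, 15.5 to 28.2) and likewise at snoRNA genes (odds ratio 17.8, 11.01 to 28.8). Reads shared between identical copies are argued against at snoRNA genes, where a median of 100% of 36-mers around the summits occur once in the genome (89% at the 128 peaks at tRNA genes), but remain a candidate explanation at tRNA genes, since those with an identical copy had an IDR peak more often than single-copy ones (23.9% against 11.9%, odds ratio 2.27, 1.32 to 3.91), a test that cannot separate copy number from how active the genes are. At the 17 peaks of single-copy tRNA genes the median was 94.8%, short of the bound set. These shares were taken over about the width of a peak, of which a tRNA gene covers a small part. A gene shared in full could thus still leave most 36-mers unique, and the 89% does not show that reads inside these genes map uniquely. At the single-copy tRNA genes, shared reads therefore cannot be told apart from signal of the gene's own. Around the tRNA genes with an IDR peak, an excess of any single E-box type by the 20 percentage points set as the bound is argued against. The smallest adjusted p was 0.291 (Fisher's exact tests), for CACATG, at 22.5% against 14.1% around tRNA genes without an IDR peak (difference 0.56 to 16.2 points). CACATG was also above the flanks at the peaks within 250 bp of a tRNA gene (Fisher's exact adjusted p = 0.0230). Contact with E-boxes at these tRNA genes stays open, because each type was tested singly and the bound of 20 points is wide. An excess of CACATG of up to 16.2 points is not excluded. Some of the tRNA genes without an IDR peak also had a pooled peak, so that they are not free of signal. Whether other proteins draw HLH-15 there, or such genes are recovered with any tagged factor, stays open, as control libraries and other factors are not analysed here.

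The second pattern is the lack of an enriched E-box type at the IDR summits. A large excess of a type just below the threshold is argued against, since in the next 4 blocks of 407 pooled peaks no type was enriched (Fisher's exact tests, smallest adjusted p = 0.442, upper bound 6.25 percentage points). An excess of the size at the IDR summits, where CAAGTG stood 4.67 points above its flanks, is not excluded. At ranks 815 to 1221 CACATG was in 7.62% against 4.30%. Pooled peaks below these blocks were not looked at. Base composition cannot be told apart from the number of control windows: CACATG passed against 4070 GC-matched windows (11.5% against 7.94%, Fisher's exact adjusted p = 0.0469), a share close to the 8.23% of the 814 flanking windows, and in 1 of 5 sets of 814 GC-matched windows (adjusted p from 0.0189 to 0.312). The excess of CACATG lay near tRNA genes: within 250 bp of one it was in 20.1% of summit windows against 8.96% of flanks. Around tRNA genes without an IDR peak CACATG was already in 14.1%, against 22.5% around those with one (Fisher's exact adjusted p = 0.291). Without the peaks at tRNA and snoRNA genes it was in 6.84%, against 8.12% of flanking and 7.22% of GC-matched windows. CAAGTG at all IDR peaks lost most of its excess against the GC-matched windows, at 12.04% against 10.15% (Fisher's exact adjusted p = 0.290). Dilution by the peaks at tRNA and snoRNA genes may account for part of the pattern, since without them CAAGTG passed, at 14.1% of summit windows against 5.98% (Fisher's exact adjusted p = 0.00553).

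The third pattern is that rise of CAAGTG at the 234 peaks, a hypothesis found and tested on the same list, and its call depends on how the peaks are chosen. In earlier looks at the 273 peaks over 250 bp from a tRNA gene it was 13.2% against 7.14% (Fisher's exact adjusted p = 0.0664), and in the strongest 130 of them 15.4% against 6.92% (adjusted p = 0.108), so that neither passed. The p-values are not adjusted for the 4 subsets of peaks looked at. Base composition cannot be told apart from a preference for the site, because against GC-matched windows the share was 14.1% against 9.06% (difference 0.43 to 9.65 percentage points, Fisher's exact adjusted p = 0.0624), and against windows matched on TSS distance 14.1% against 9.49% (adjusted p = 0.0966). The labels give 1 group, so no explanation by a difference between groups was tested.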
